A study of Mus musculus with 39 samples.

How the data were processed

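RNA was measured in sorted mouse bone marrow cells. Per the labels, 6 populations were sorted from Mx1-Elk1 transgenic mice and from control mice, with 3 samples per population and genotype and 3000 cells per sample. LSK cells are lineage-negative, Sca1-positive, cKit-positive cells, the fraction that holds haematopoietic stem and multipotent progenitor cells. CMP are common myeloid progenitors, GMP granulocyte-monocyte progenitors and MEP megakaryocyte-erythrocyte progenitors. ImmN and MatN are sorted immature and mature neutrophils. Per the labels' protocols, polyA RNA was turned into double-stranded cDNA by a low-input amplification procedure, libraries were built with a tagmentation kit, and sequencing was done on a NovaSeq X plus. Amplified reads without molecular identifiers are not independent molecules, and no identifiers are described for the bulk libraries. The labels call the controls littermates in one place and wild-type mice in another, and do not identify single animals. The p-values therefore measure the spread between these samples, which may be technical. The labels do not describe the transgene's sequence or say when it was induced. Nor do they say whether it raises or lowers Elk1 function. The single-cell samples that the labels also list were not analysed here.

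The values are a table of CPM made by the authors, in which each gene's reads are scaled to the library's total. The submitters' processing notes name featureCounts, which assigns aligned reads to genes, without a version, the genome build mm10, and Cell Ranger 4.0.4, a single-cell tool. The aligner, the gene annotation and the strand setting are not given in the sources used here. The table holds 30815 gene symbols. Of these, 91.4% matched a symbol of the GENCODE vM21 annotation of the same build, from which gene positions were taken. The table has 35 columns whose names match a labelled sample. It has 1 more column without a sample name, which was not used in any step, so MatN from Mx1-Elk1 mice had 2 libraries (replicates 1 and 3). CPM divides each gene by its library's total, so a gene's value falls when a few others take more of the reads, and genes with near-identical copies or overlapping neighbours (such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, the Xlr4 genes and the immunoglobulin segments) can share or lose reads in the counting.

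In every column used, all values (100%) were whole multiples of the worth of 1 read, within 0.1 read, so the reads per gene and the depth were recovered. Totals were 8907787 to 24029589 reads in 23 of the progenitor libraries and 1498657 to 3116807 in the 11 neutrophil libraries. In these, 1 read was worth 0.0416 to 0.112 CPM and 0.321 to 0.667 CPM respectively. Levels of a few CPM in the neutrophil libraries thus rest on few reads. Where a group had no read of a gene, the level that 3 reads over the group's libraries would give is stated as the limit, which covers counting error only. A chi-square comparison of replicate libraries over genes gave at least 12.1 per degree of freedom, which does not show that they came from separate animals.

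A gene near the floor in most populations would lower a spread shared by all libraries, so each population was fitted by itself. For each population, Mx1-Elk1 was compared with Ctrl in the libraries of that population alone. Genes with at least 1 CPM in at least 3 of its libraries were tested with limma 3.58.1 (R 4.3.3) on log2(CPM + 1), with an intensity trend in the prior, two-sided, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Log2 differences are Mx1-Elk1 minus Ctrl on this scale unless another contrast is named, and understate the change of genes with low values. A value after ± is the standard error for a log2 difference of a gene and the SD for CPM and for marker means. MatN was compared with ImmN in each genotype, and the difference between these contrasts was tested, in a fit of the 11 neutrophil libraries. Single values were also compared by exact two-sided permutation tests. With 3 libraries against 3, or 3 against 2, the smallest exact p is 0.1. The design named edgeR as the main test only if the file had held counts. edgeR 4.0.16 (quasi-likelihood) was therefore run on the recovered reads as an alternative.

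Before the data were examined, 26 gene lists with 470 symbols were fixed, of which 12 symbols were not in the table. They were: stem and multipotent progenitor, primary granule, specific granule, gelatinase granule and secretory vesicle, mature neutrophil, myeloid transcription factor, S phase, G2 and M phase, type I interferon response, immediate early (targets of the ternary complex factors and SRF), SRF and MRTF cytoskeletal, NADPH oxidase, chemotaxis and trafficking receptor, inflammatory cytokine and NF-kB, p53 target, heat shock and unfolded protein response, oxidative phosphorylation, glycolysis, ribosomal protein, erythroid, megakaryocyte and platelet, monocyte and macrophage, dendritic and MHC class II, B lineage, T and NK cell, and basophil, mast cell and eosinophil genes. Lists with at least 5 tested members were tested with camera (limma) at its preset correlation of 0.01 and adjusted over the lists of a comparison. The estimated correlation was the alternative. With the preset, 19 lists were called in LSK, 17 in CMP, 9 in GMP, 12 in MEP, 4 in ImmN and 12 in MatN. With the estimated correlation 6 held in LSK, 3 in CMP and 0 in the other populations.

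The rule for named genes was also fixed before the data were examined. For each population it took the called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted models and clones, and named the 12 largest differences of each sign in ImmN and MatN and the 6 largest in the progenitors. Where none passed, it named the 3 of each sign with the smallest p as not passing. Called list members (up to 4 per list) and a set of key genes were named besides. Marker genes of each population and of other marrow cells were read in every library as a check of the sort labels.

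The alternatives were a pseudocount of 0.25 CPM, no filter on low values, CPM rescaled by TMM factors, a single fit of all libraries, the replicate number as a block, edgeR, a minimum log2 difference of 1, linear CPM for Elk1, and leaving out each library in turn. Leaving out the library labelled Mx1-Elk1 MEP replicate 1 was thus planned, but its use as a second MEP comparison with its own alternatives, and the weight given to the Elk1 test without it, were decided after the data were seen. So were the progenitor comparisons without genes far higher in neutrophil libraries. The last set holds the 2266 genes with a mean of at least 20 CPM in the 11 neutrophil libraries that was at least 20 times their mean in the 23 progenitor libraries.

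The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison. All genes of a comparison were given a common dispersion, so the shares below do not describe single genes. limma recovered 41% of the 2-fold and 100% of the 4-fold changes in LSK, 21% and 97% in CMP, and 3% and 74% in GMP. In MEP it recovered 0% and 1% with 6 libraries, and 24% and 97% without the library labelled Mx1-Elk1 MEP replicate 1. In ImmN it recovered 1% and 0%, and in MatN 0% of either. No simulated change was recovered in the comparisons of MatN with ImmN or in the test of their difference.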

Results

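The data were 35 libraries of sorted bone marrow cells from mice carrying an Mx1-Elk1 transgene and from control (Ctrl) mice, covering LSK, CMP, GMP, MEP, ImmN and MatN cells. ELK1 is a transcription factor of the ternary complex factor family, which acts with SRF at the promoters of immediate early genes. The series' title concerns the maturation of neutrophils, and its design text asks how Elk1 acts in blood cell formation. Every group had 3 libraries except MatN from Mx1-Elk1 mice, which had 2. Between 11427 and 12928 genes reached 1 CPM in 23 of the progenitor libraries, and between 15836 and 23704 in the 11 neutrophil libraries.

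Markers of 1 library did not match its label, and some neutrophil libraries carried more progenitor markers than others. Klf1, an erythroid transcription factor, stood at 645 ± 56.4 CPM (SD, n = 3) in Ctrl MEP and 7.23 ± 3.96 CPM in Ctrl LSK. S100a9, an abundant neutrophil calcium-binding protein gene, was between 5235 and 26622 CPM in the 11 neutrophil libraries. The library labelled Mx1-Elk1 MEP replicate 1 had 13.2 CPM of Klf1, 8667 CPM of S100a9 and 628 CPM of Retnlg, a gene of mature neutrophils. Its mature neutrophil marker mean was 6.85 on the log2(CPM + 1) scale, within the 3.65 to 7.72 of the neutrophil libraries and above the 1.08 to 1.82 of the other 5 MEP libraries. Its MEP marker mean was 4.68, above the 2.24 to 4.24 of the neutrophil libraries and below the 7.62 to 8.18 of the other 5 MEP libraries. It had 1587586 reads and 24081 genes at 1 CPM or more. It is called the library labelled Mx1-Elk1 MEP replicate 1 throughout, and the MEP comparison is given with and without it. GMP marker means were 9.63 in Ctrl ImmN replicate 3, 7.51 and 7.23 in Mx1-Elk1 ImmN replicates 1 and 2 and 8.44 in Mx1-Elk1 MatN replicate 1, against 4.10 to 5.92 in the other 7 neutrophil libraries. Ctrl ImmN replicate 3 also had a basophil and mast cell marker mean of 5.65 (1.04 and 0.589 in the other Ctrl ImmN libraries). Genes of other lists stood high in all 11 neutrophil libraries. Cd3e (T and NK cell) was at 252 to 1218 CPM there and Vwf (megakaryocyte) at 446 to 1429 CPM. The 2266 genes far higher in neutrophil libraries took 33.4 to 51.3% of their reads. Of these genes, 2251 were on none of the granule, mature neutrophil, chemotaxis, NADPH oxidase and inflammatory cytokine lists. The source of these reads was not tested, so a high level there need not be neutrophil expression.

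**Figure D1:**
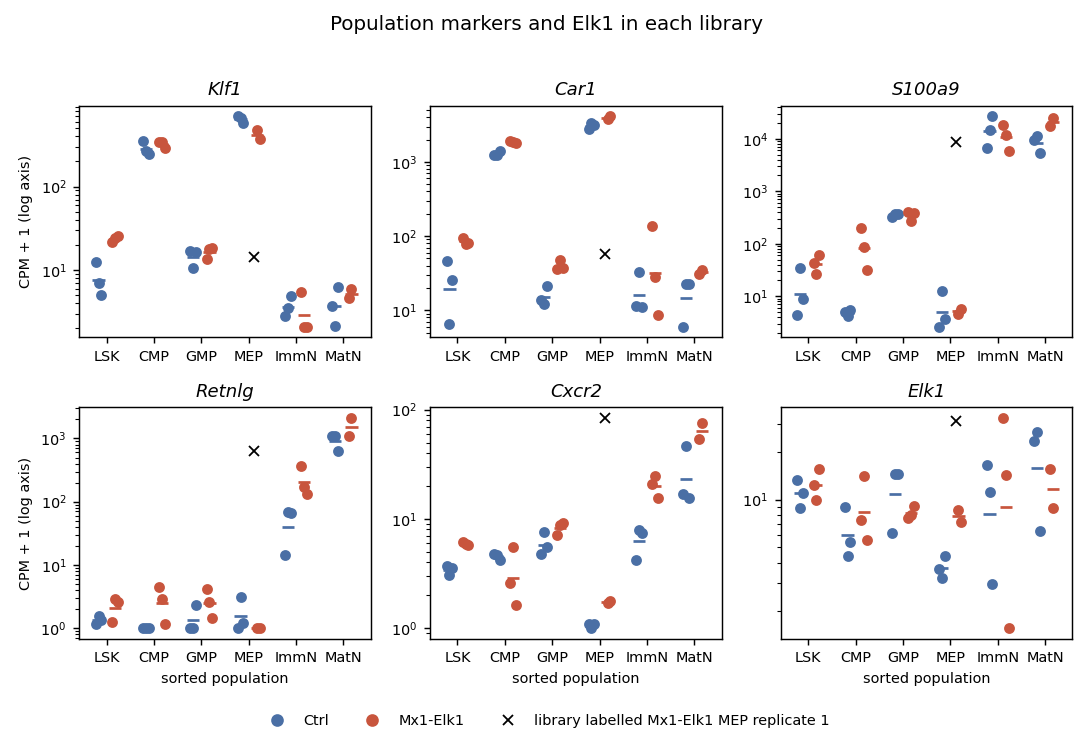
CPM + 1 (log axis) of 5 marker genes and Elk1 in each of the 35 libraries, by sorted population; blue points are Ctrl, red points Mx1-Elk1, short lines the means of log2(CPM + 1), and the cross is the library labelled Mx1-Elk1 MEP replicate 1. The cross lies with the neutrophil libraries for S100a9 (8667 CPM) and Retnlg (628 CPM) and far below the other MEP libraries for Klf1 (13.2 CPM).

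Elk1 itself (chromosome X, 20933395 to 20950608, minus strand, mm10) was not called in any population. It was 10.1 ± 2.23 against 11.6 ± 2.86 CPM in LSK (Ctrl against Mx1-Elk1, mean ± SD, n = 3 each), 5.25 ± 2.41 against 8.00 ± 4.42 in CMP and 10.6 ± 4.77 against 7.26 ± 0.756 in GMP. In ImmN it was 9.19 ± 6.86 against 15.2 ± 15.6, and in MatN 17.8 ± 10.95 against 11.2 ± 4.66 CPM (n = 3 and 2). In MEP it was 2.75 ± 0.595 CPM in Ctrl and 6.91 ± 1.04 in the other 2 libraries labelled Mx1-Elk1, a difference of 1.08 ± 0.38 (SE) with a limma adjusted p of 0.113 and an exact p of 0.1, the smallest possible. Over all 6 populations the mean difference was 0.29 (exact stratified permutation p = 0.395), and 0.18 without the library labelled Mx1-Elk1 MEP replicate 1 (exact p = 0.565). Reads of a transgene are counted as Elk1 only if its sequence matches the annotated gene, which the labels do not settle. Of the other ternary complex factors, Elk4 was lower in LSK, at 153 ± 4.30 against 111 ± 7.62 CPM (-0.46 ± 0.11, limma adjusted p = 0.00772). Elk3 was not called in any population, nor was Elk4 outside LSK.

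In LSK, Mx1-Elk1 libraries had less RNA of stem cell genes and more of myeloid and B-lymphoid progenitor genes. The LSK marker mean was 7.50 ± 0.04 in Ctrl and 6.28 ± 0.17 in Mx1-Elk1 LSK. The GMP marker mean was 6.06 ± 0.08 and 8.09 ± 0.14, and the monocyte marker mean 3.37 ± 0.10 and 4.99 ± 0.07. Mpl, the thrombopoietin receptor, fell from 390.4 ± 18.2 to 51.0 ± 17.8 CPM (-2.98 ± 0.18, n = 3 each, limma adjusted p = 3.9e-09), and the stem cell factor Hlf from 265 ± 28.7 to 75.8 ± 5.18 CPM. Elane, encoding neutrophil elastase, rose from 63.7 ± 11.4 to 633 ± 113 CPM (3.29 ± 0.14, limma adjusted p = 3.6e-11), and Mpo, encoding myeloperoxidase, from 495 ± 124 to 1869 ± 102 CPM. Of the 17 stem and multipotent progenitor genes, 14 fell and 3 rose, among them Flt3, which marks multipotent progenitors (median -1.58, camera adjusted p = 1.6e-07). The list's call was lost at adjusted p = 0.0741 with an estimated correlation. Of the 10 primary granule genes 8 rose and 2 fell (median 1.18), and of 14 mature neutrophil genes 7 rose, including Trem3 (3.04 ± 0.29), Sell, Sorl1 and Slpi. Both calls held with an estimated correlation (adjusted p = 0.0418 and 0.0380). Adjusted over the list alone, the counts were 8 and 2 for primary granule genes, and 9 for mature neutrophil genes. The haptoglobin gene Hp rose from 1.62 ± 0.604 to 26.7 ± 12.8 CPM, 1 of 2 specific granule genes that rose among 7 tested, beside Wfdc21 (adjusted p = 0.115 with an estimated correlation). Monocyte genes moved with them: 7 of 15 rose and none fell (adjusted p = 0.0418 with an estimated correlation), including Ly6c2 from 35.5 ± 17.9 to 199.7 ± 27.0 CPM and the M-CSF receptor Csf1r from 8.08 ± 3.23 to 18.1 ± 1.39 CPM. Of 12 chemotaxis and trafficking receptor genes 7 rose and 1 fell (adjusted p = 0.0418 with an estimated correlation).

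Cell cycle genes rose in the LSK libraries as well, by smaller steps. Of 24 S phase genes 13 rose and 1 fell, and of 25 G2 and M phase genes 12 rose (adjusted p = 0.0535 and 0.0834 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, went from 81.0 ± 10.0 to 171 ± 19.0 CPM, and Mki67 from 119.5 ± 18.9 to 171 ± 11.9 CPM. Type I interferon response genes went the other way: 12 of 24 fell and 1 rose (median -0.51, adjusted p = 0.107 with an estimated correlation), with Ifit1 from 36.7 ± 9.53 to 14.5 ± 3.38 CPM and Rsad2 from 91.3 ± 12.2 to 34.4 ± 4.78 CPM. Of 19 immediate early genes 11 rose and 2 fell, and of 16 heat shock and unfolded protein response genes 8 rose; both calls held with an estimated correlation (adjusted p = 0.0488 and 0.0380). Egr1 rose from 298 ± 21.2 to 499 ± 18.0 CPM, while Fos was at 718 ± 37.9 and 786 ± 92.1 CPM and was not called. B lineage genes rose in 7 of 10 cases and fell in 1 (median 1.55, adjusted p = 0.0910 with an estimated correlation). The pre-B receptor gene Igll1 had the largest increase, from 1.38 ± 0.809 to 28.6 ± 4.06 CPM (3.69 ± 0.34). Dntt, which encodes the terminal transferase of early lymphoid cells, went from 123 ± 14.3 to 427 ± 4.36 CPM. Trbc1, a T cell receptor constant segment, had no read in Ctrl, which allows up to 0.0551 CPM, and 10.2 ± 4.57 CPM in Mx1-Elk1. Megakaryocyte and platelet genes fell in 5 of 10 cases (adjusted p = 0.0634 with an estimated correlation), with Vwf from 26.7 ± 1.99 to 7.97 ± 2.47 CPM. Vwf belongs to the set far higher in neutrophil libraries, where it averaged 965 CPM. Of the 8 oxidative phosphorylation genes that rose among 29, the largest step was 0.62 ± 0.13 for Cycs (adjusted p = 0.0634 with an estimated correlation).

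Immunoglobulin genes had the largest decreases in LSK. Igha, the IgA constant segment, fell from 1572 ± 250.3 to 18.5 ± 32.0 CPM, Igkc from 2426 ± 580.3 to 45.9 ± 78.9 and Jchain, which joins IgA and IgM units, from 613 ± 124 to 15.5 ± 26.8 CPM. These are genes of plasma cells. Igkv10-96 and Iglc2, a kappa variable and a lambda constant segment, fell as well (-7.38 ± 0.68 and -4.93 ± 0.90). Ighv1-72 was at 31.3 ± 2.34 CPM in Ctrl and had no read in the 3 Mx1-Elk1 libraries, which allows up to 0.0506 CPM, so it was at least 619-fold lower. In each of the 3 Ctrl libraries, Ighv1-72 and Igkv10-96 were the leading heavy and kappa variable segments. The labels do not say whether these 3 libraries came from separate animals. The immunoglobulin differences therefore need not be differences between the genotypes, and the LSK p-values may rest on libraries that are not independent.

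In all, 2127 of 12215 genes were called in LSK, 692 higher and 1435 lower. With TMM scaling the split was 1098 higher and 1134 lower, and the median gene moved from -0.09 to 0.00. edgeR called 1924. The count was 963 without the filter on low values and 52 in a single fit of all libraries, and 1255 and 1383 without Mx1-Elk1 LSK replicate 2 and Ctrl LSK replicate 2.

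In CMP, B-lymphoid and immediate early genes were higher in Mx1-Elk1 and primary granule, monocyte and MHC class II genes lower. The B cell genes Cd19 and Ebf1 rose from 3.36 ± 1.80 to 43.3 ± 3.21 and from 2.50 ± 0.841 to 36.6 ± 8.79 CPM (3.44 ± 0.35 and 3.43 ± 0.35, n = 3 each, limma adjusted p = 5.4e-06 and 5.2e-06). Of 11 B lineage genes 9 rose, and all 11 adjusted over the list alone (median 2.74, camera adjusted p = 7.7e-31). The call held at adjusted p = 0.0276 with an estimated correlation. The B cell marker mean was 2.84 ± 0.38 in Ctrl and 5.06 ± 0.42 in Mx1-Elk1 CMP. Mpo fell from 1488 ± 267 to 529.7 ± 39.2 CPM (-1.47 ± 0.17, limma adjusted p = 2.1e-05) and Elane from 111 ± 18.1 to 23.0 ± 3.22 CPM. Of 10 primary granule genes 5 fell, and 7 adjusted over the list alone (adjusted p = 0.0498 with an estimated correlation). The same count of 5 of 10 fell among dendritic and MHC class II genes, with Cd74, the invariant chain, from 49.7 ± 8.03 to 3.41 ± 1.62 and H2-Aa from 131 ± 16.6 to 40.5 ± 6.06 CPM (adjusted p = 0.0498 with an estimated correlation). Of 12 monocyte and macrophage genes 4 fell, and 10 adjusted over the list alone (adjusted p = 0.0849 with an estimated correlation), with Ly6c2 from 246 ± 23.6 to 77.6 ± 13.4 CPM. The myeloid regulators Irf8, Cebpa and Spi1 were the 3 myeloid transcription factor genes of 19 that fell, a list that was not called (camera adjusted p = 0.109).

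Immediate early genes rose in 9 of 19 cases in CMP (median 0.45, camera adjusted p = 7.3e-10, adjusted p = 0.105 with an estimated correlation). Egr3 went from 1.13 ± 1.16 to 27.6 ± 9.27 CPM, Egr2 from 8.11 ± 3.499 to 54.7 ± 12.9 and Fos from 311 ± 72.3 to 541 ± 97.1 CPM. Dnajb1 and Hsph1 of the heat shock list rose and Calr fell (adjusted p = 0.0849 with an estimated correlation). Specific granule genes rose in 3 of 8 cases (Camp, Ngp and Chil3), but the list's call was lost at adjusted p = 0.161 with an estimated correlation. S100a8 and S100a9, also products of later neutrophil stages, had the largest increases, with S100a9 from 3.92 ± 0.634 to 104 ± 83.4 CPM. Both, like Camp, Ngp and Chil3, belong to the set far higher in neutrophil libraries. The immature neutrophil marker mean, which includes Camp, Ngp and Chil3, was 0.64 ± 0.20 in Ctrl and 2.23 ± 0.65 in Mx1-Elk1 CMP. The mature neutrophil marker mean was 2.71 ± 0.02 and 2.62 ± 0.38. Of the 6 genes with the largest decreases, Tmem117 (22.0 ± 1.69 to 0.344 ± 0.365 CPM), Hsf5, Mcmdc2 and Rian belong to the set far higher in neutrophil libraries, where Tmem117 averaged 791.9 CPM. Insl5 was at 9.20 ± 1.17 CPM in Ctrl and had no read in Mx1-Elk1, which allows up to 0.0471 CPM.

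In all, 363 of 11936 genes were called in CMP, 126 higher and 237 lower, and 147 and 181 with TMM scaling. edgeR called 276. Without the genes far higher in neutrophil libraries 249 were called, 61 without the filter on low values and 27 in a single fit of all libraries. Leaving out Ctrl CMP replicate 1, 2 or 3, or Mx1-Elk1 CMP replicate 1, gave 208, 156, 173 and 233. The split was 77 higher and 79 lower without Ctrl CMP replicate 2 and 99 and 74 without replicate 3. More calls were lower when any other library was left out.

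In GMP, immediate early genes rose and no gene of the granule lists was called. Fos rose from 99.8 ± 16.7 to 426 ± 53.8 CPM (2.09 ± 0.18, n = 3 each, limma adjusted p = 0.00179), Egr1 from 107 ± 23.3 to 392 ± 36.8 CPM (1.88 ± 0.20, limma adjusted p = 0.00276) and the nuclear receptor Nr4a1 from 7.03 ± 2.61 to 52.5 ± 8.65 CPM. Of 19 immediate early genes 8 rose, and 14 adjusted over the list alone (median 1.24, camera adjusted p = 9.4e-19). The call was lost at adjusted p = 0.121 with an estimated correlation. Socs3, an inhibitor of cytokine signalling, rose from 0.620 ± 0.343 to 8.83 ± 1.39 CPM, and Angptl2 and the X-linked Xlr4c rose too. Tnf and Cxcl2 rose among 15 inflammatory cytokine and NF-kB genes (adjusted p = 0.121 with an estimated correlation), and Dnajb1 rose among 18 heat shock genes (adjusted p = 0.594 with an estimated correlation). The basophil protease genes Prss34 and Mcpt8 fell, Prss34 from 407 ± 113 to 66.8 ± 5.37 CPM; 9 other genes of that list were not called (adjusted p = 0.121 with an estimated correlation). Mpo was at 19572 ± 3435 CPM in Ctrl and 17749 ± 1558 in Mx1-Elk1, and Elane at 9223 ± 1861 and 8420.1 ± 614 CPM. Neither was called, nor was any of 10 primary granule, 10 specific granule and 8 gelatinase granule genes (medians -0.087, 0.31 and 0.17, camera adjusted p = 0.532, 0.133 and 0.925). Adjusted over the list alone 0, 0 and 1 (lower) were called by limma. In GMP 3% of simulated 2-fold changes were recovered, with a common dispersion of 0.149 for all genes. That share does not describe the granule genes singly. Of 14 p53 target genes 0 were called by limma, and 0 adjusted over the list alone (median 0.45, adjusted p = 0.201 with an estimated correlation).

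The 6 largest decreases in GMP were Tmem117 (102 ± 21.3 to 1.28 ± 0.486 CPM), Aqp7, Ankub1, Fstl1, Ckmt1 and Wt1, all in the set far higher in neutrophil libraries. In all, 132 of 12204 genes were called, 23 higher and 109 lower, and 20 (10 higher, 10 lower) without that set. edgeR called 82 and kept 11 of the 20 genes of GMP that the naming rule took, with Egr2, Egr3, Egr4, Angptl2, Xlr4c, Cxcl2, Ankub1, Fstl1 and Ckmt1 lost. The count was 39 without the filter and 18 in a single fit of all libraries. Leaving out Ctrl GMP replicates 1, 2 and 3 gave 51, 29 and 299, and leaving out Mx1-Elk1 GMP replicates 1 and 2 gave 36 and 34. Ctrl GMP replicate 3 stood apart, with a chi-square per degree of freedom of 146 and 111 against replicates 1 and 2 (23.7 between these). Mitochondrial genes took 0.605% of its reads, against 2.06 and 1.71%.

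In MEP, no gene was called by limma or by edgeR among 12095 when all 6 libraries were used, with 755 at an unadjusted limma p under 0.05 and 1282 by edgeR. The genes with the smallest p, which did not pass, were Slamf6, Akap12 and Pde2a among those higher and Insl5, Hba-a1 and Sh3tc2 among those lower. Of the lists, 12 were called with the preset correlation and none with the estimated one (smallest adjusted p = 0.298). The following MEP values are without the library labelled Mx1-Elk1 MEP replicate 1 and compare 3 Ctrl libraries with 2. That fit was among the planned ones that leave out a library, and was chosen for this fuller account after the data were seen.

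B lineage genes were then higher and erythroid genes lower in Mx1-Elk1 MEP. Cd19 rose from 8.60 ± 2.29 to 80.8 ± 0.565 CPM (3.12 ± 0.27, limma adjusted p = 1.4e-06), the B cell regulator Pax5 from 5.06 ± 3.88 to 55.2 ± 10.4 CPM, and Cd79a from 8.30 ± 2.84 to 74.2 ± 17.3 CPM. All 11 B lineage genes tested rose (median 2.72, camera adjusted p = 2.6e-31, adjusted p = 0.0592 with an estimated correlation). The B cell marker mean was 3.69 ± 0.25 in Ctrl and 6.39 ± 0.16 in the 2 Mx1-Elk1 libraries. Of 18 erythroid genes 11 fell (adjusted p = 0.0592 with an estimated correlation), including the alpha-globin gene Hba-a1 from 130.4 ± 44.5 to 19.5 ± 1.64 CPM and the beta-globin gene Hbb-bs from 40.7 ± 10.6 to 6.96 ± 4.44 CPM. The aminopeptidase gene Enpep had the largest increase (3.94 ± 0.46), followed by Pax5, Xlr4c, Ighd, Pou2af1 and Tnfrsf19. Insl5 fell from 32.3 ± 3.49 to 0.355 ± 0.133 CPM, ahead of Slc15a2, Ankub1, Tmem117, Fbxw8 and Mtus2. Immediate early genes rose in 11 of 17 cases (median 1.02, adjusted p = 0.168 with an estimated correlation), with Fos from 208 ± 62.4 to 562 ± 68.5 CPM. S phase genes fell in 5 of 24 cases, with Mcm5 from 682 ± 51.3 to 259.7 ± 8.05 CPM (adjusted p = 0.109 with an estimated correlation), and 4 of 10 primary granule genes rose (adjusted p = 0.106 with an estimated correlation). Ccl5, Klrb1c and Lck rose among 5 T and NK cell genes (adjusted p = 0.146 with an estimated correlation).

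In that fit 620 of 11476 genes were called, 361 higher and 259 lower, and edgeR called 506. The count was 575 without the genes far higher in neutrophil libraries, 182 without the filter and 59 in a single fit of all libraries. Leaving out Ctrl MEP replicates 2 and 3 gave 977 and 334, and leaving out Mx1-Elk1 MEP replicates 2 and 3 gave 186 and 160, where the lone library is assumed to vary like the others.

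**Figure D2:**
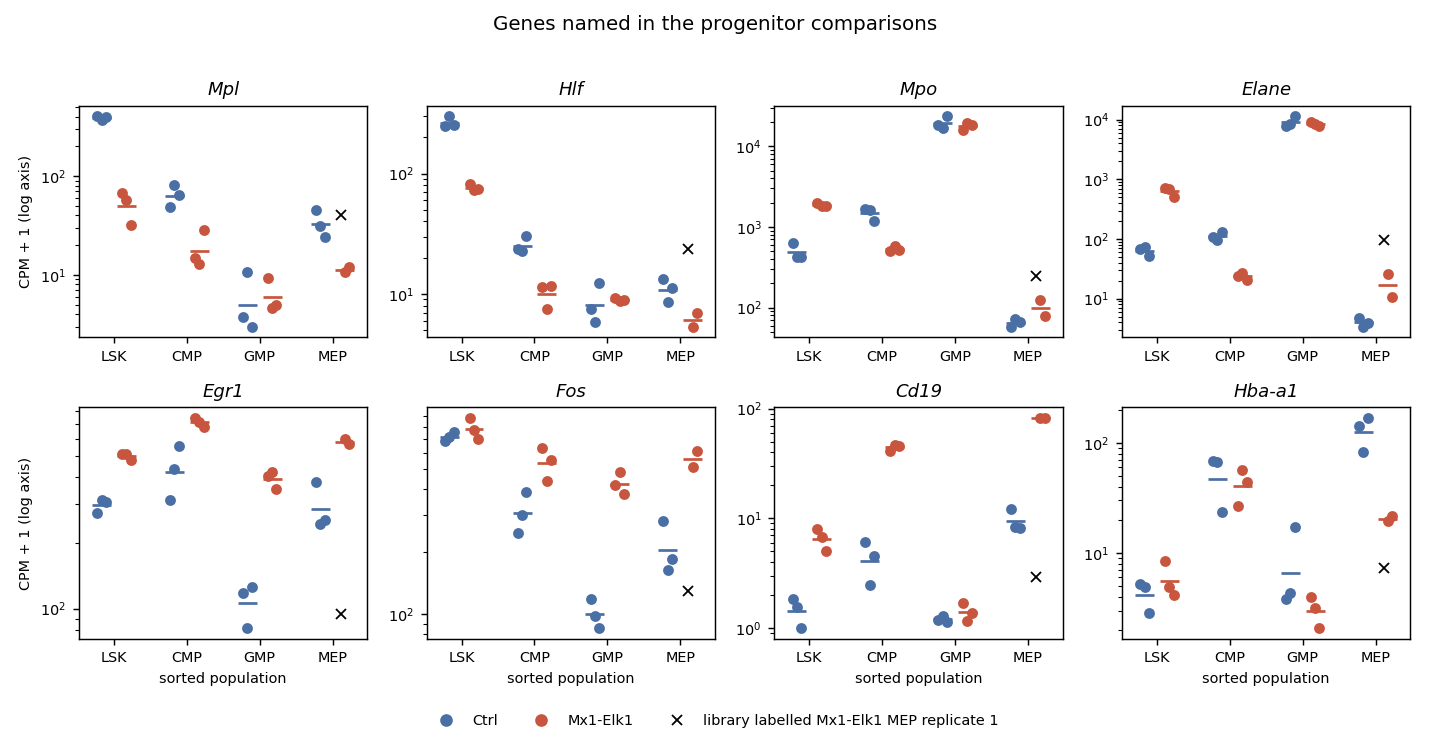
CPM + 1 (log axis) of 8 genes in each library of the 4 progenitor populations; blue points are Ctrl, red points Mx1-Elk1, short lines the means of log2(CPM + 1) without the cross, and the cross is the library labelled Mx1-Elk1 MEP replicate 1. Elane is higher in Mx1-Elk1 LSK (633 against 63.7 CPM) and lower in Mx1-Elk1 CMP (23.0 against 111 CPM), and Egr1 is higher in Mx1-Elk1 in each population when the cross is left out.

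Calls overlapped between progenitor populations more than independent lists would. The labels do not say whether the populations share animals, so this excess need not be a common response to the genotype. Of genes tested in both, 93 were higher in CMP and in MEP (without the library labelled Mx1-Elk1 MEP replicate 1), where 3.79 were expected, and 112 in LSK and in MEP, where 19.3 were expected. LSK and CMP shared 49 higher calls (6.20 expected), while 34 genes higher in LSK were lower in CMP. CMP and GMP shared 42 lower calls (1.66 expected) and 8 (0.294 expected) without the genes far higher in neutrophil libraries. Among 10721 genes tested in all 4 progenitor populations, 10 were higher in all 4: the immediate early genes Btg2, Egr1, Egr2 and Nr4a1, and Dnajb1, Tnf, Gdf3, Marcksl1, Xlr4c and 1700048O20Rik. Of 12 genes lower in all 4, the named ones were Ankub1, Aqp7, Ctse, Fsd2, Fstl1, Hsf5, Ly6k, Tmem117, Vill and Wdfy1. Both sets were listed after their values were seen. Counting calls in at least 3 populations, 37 genes were higher and 32 lower. Of the latter 15, and of the former 0, were in the set far higher in neutrophil libraries.

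**Figure D3:**
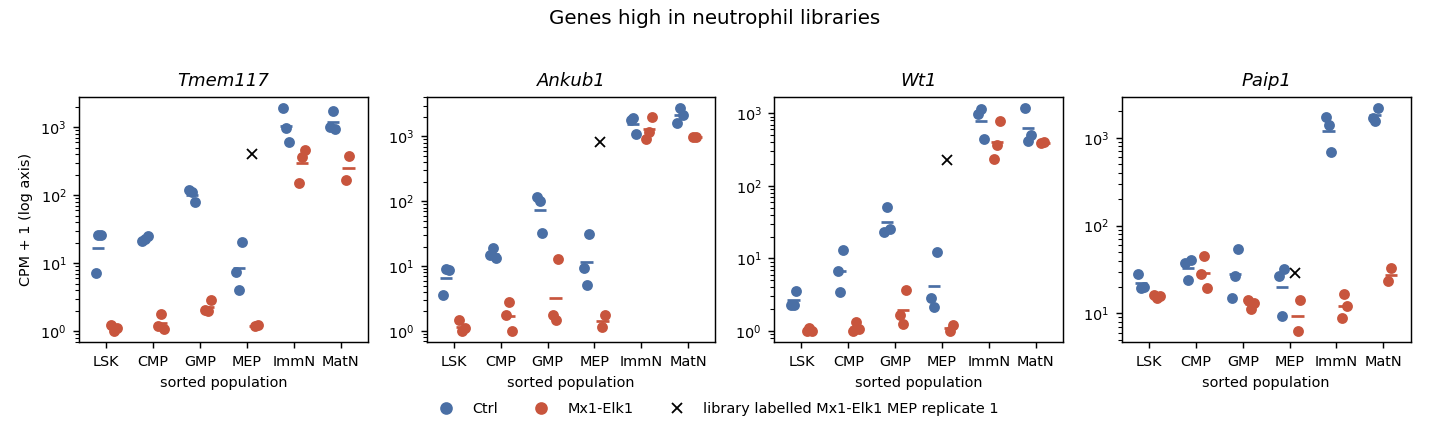
CPM + 1 (log axis) of 4 genes far higher in neutrophil libraries, in each library by sorted population; blue points are Ctrl, red points Mx1-Elk1, short lines the means of log2(CPM + 1) without the cross, and the cross is the library labelled Mx1-Elk1 MEP replicate 1. Tmem117 stands at 22.0 CPM in Ctrl and 0.344 CPM in Mx1-Elk1 CMP, and Paip1 at 1268 CPM in Ctrl and 11.5 CPM in Mx1-Elk1 ImmN.

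In ImmN, Paip1 was the 1 gene called among 20946 by limma, and edgeR called it alone as well. Paip1 (chromosome 13, 119428601 to 119458218, plus strand, mm10) encodes a protein that binds the poly(A)-binding protein and acts in translation. It fell from 1268 ± 523 to 11.5 ± 3.90 CPM (-6.62 ± 0.50, n = 3 each, limma adjusted p = 2.2e-04). At an unadjusted p under 0.05 limma had 2430 genes and edgeR 2025. Granule genes did not pass: Ltf was at 1823 ± 1173 in Ctrl and 1072 ± 578 CPM in Mx1-Elk1, and Camp at 5685 ± 3199 and 2608 ± 1369 CPM. The list of 13 specific granule genes had a median of -1.09 with 0 called, 0 adjusted over the list alone and camera adjusted p = 2.2e-04, lost at adjusted p = 0.9705 with an estimated correlation. S phase, SRF and MRTF cytoskeletal and ribosomal protein lists were also lower with the preset and lost with the estimated correlation at the same p. Ctrl ImmN replicate 3 stood apart, with a GMP marker mean of 9.63 (4.49 and 5.47 in the other Ctrl ImmN libraries) and 6.64% of its reads in ribosomal protein genes against 0.994 and 1.20%. Without it the ribosomal protein median turned from -0.61 to 0.49. Cxcr2, the receptor that releases neutrophils from marrow, was at 5.52 ± 2.03 and 19.4 ± 4.77 CPM and was not called. Mx1-Elk1 ImmN libraries had 21259 to 22722 genes at 1 CPM or more, against 15836 to 18301 in Ctrl. Leaving out Mx1-Elk1 ImmN replicate 1, 2 or 3 gave 13, 10 and 18 called genes, and leaving out Ctrl ImmN replicate 3 gave 2. A single fit of all libraries, with each gene's spread shared over all populations, gave 2528.

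In MatN, with 3 Ctrl and 2 Mx1-Elk1 libraries, Paip1 fell again, from 1818 ± 338 to 27.2 ± 7.07 CPM (-6.02 ± 0.34, limma adjusted p = 1.2e-10). Of 19772 genes 144 were called, 56 higher and 88 lower, but edgeR called 3, all lower. With the replicate number as a block 124 were higher and 108 lower, but Ctrl MatN replicate 2 then had no partner and did not enter the difference. TMM scaling gave 39 and 87, and a pseudocount of 0.25 CPM 11 and 29. edgeR kept 2 of the 31 genes that the naming rule took here, Paip1 and Ighv1-14. Ighv1-14, an immunoglobulin heavy variable segment, was at 61.8 ± 26.6 CPM in Ctrl and had no read in Mx1-Elk1, which allows up to 0.778 CPM. By limma alone, genes that rose included Plek, a pleckstrin of blood cells (6.999 ± 5.73 to 98.1 ± 33.1 CPM), Abracl (2.25 ± 2.05 to 68.6 ± 46.4), Rab32, Rap1b, Cnih1, Selenot, Tmem50b, Ndufa1, Rsrp1, Pilrb1, Lmo1 and Epm2aip1. Those that fell by limma alone were Masp2 (346 ± 10.96 to 44.4 ± 27.5 CPM), Arhgef5, Slc9a3, Srrd, Ube2t, Tmub2, St8sia2, Kcnj8, Xndc1 and Rad52.

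Granule and housekeeping lists were higher in Mx1-Elk1 MatN with the preset correlation only. The 2 Mx1-Elk1 libraries were unlike each other: the GMP marker mean was 8.44 in replicate 1 and 5.92 in replicate 3 (4.10 to 5.86 in Ctrl MatN), and ribosomal protein genes took 4.58 and 1.14% of the reads (0.826 to 1.07% in Ctrl MatN). Of 40 ribosomal protein genes 1 was called, and 34 adjusted over the list alone (median 1.60, camera adjusted p = 6.9e-23, adjusted p = 0.374 with an estimated correlation). Of 10 primary granule genes 0 were called, and 7 adjusted over the list alone (median 2.37, adjusted p = 0.374 with an estimated correlation), with Elane at 76.9 ± 44.8 and 659 ± 805 CPM. Specific granule genes had a median of 1.05 with 0 called and 5 adjusted over the list alone, and gelatinase granule genes 1.15 with Mmp9 called (122 ± 6.74 to 410.1 ± 76.1 CPM). Fos rose from 25.3 ± 3.59 to 162 ± 65.2 CPM, the 1 call among 17 immediate early genes. NADPH oxidase, glycolysis and oxidative phosphorylation lists were higher by the preset too, with medians of 1.11, 0.88 and 1.44. Every one of these was lost at adjusted p = 0.374 with an estimated correlation. Mx1-Elk1 MatN libraries had 20425 to 23704 genes at 1 CPM or more, against 18384 to 19143 in Ctrl. The count of calls was 40 at a pseudocount of 0.25 CPM, 2 without the filter and, with each gene's spread shared over all populations, 1059 in a single fit of all libraries. Without Ctrl MatN replicates 1, 2 and 3 it was 29, 2 and 33, and without Mx1-Elk1 MatN replicate 3 it was 306, where the lone Mx1-Elk1 library is assumed to vary like the Ctrl libraries.

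The step from ImmN to MatN was compared within each genotype. The called genes of this comparison are given after their values were seen. In Ctrl 4 of 24923 genes were called: Retnlg rose from 49.1 to 950.2 CPM (mean, n = 3 each; 4.51 ± 0.54, limma adjusted p = 9.7e-04), while the specific granule genes Chil3 and Camp and the MHC class II gene H2-Ab1 fell (-4.15 ± 0.60, -2.63 ± 0.41 and -6.00 ± 0.97). The specific granule list fell (2 of 13 called, 9 adjusted over the list alone, median -1.78, adjusted p = 0.333 with an estimated correlation), and the mature neutrophil list was higher with 0 of 18 called and 2 adjusted over the list alone (adjusted p = 0.480 with an estimated correlation). edgeR called 6 genes. Without Ctrl ImmN replicates 1 and 2 the count was 7 and 1, and without Ctrl MatN replicates 1, 2 and 3 it was 2, 1 and 2. In Mx1-Elk1 Ly6g, the surface antigen by which mature neutrophils are commonly recognised, was the 1 gene called by limma, from 4.55 CPM in ImmN (n = 3) to 171 CPM in MatN (n = 2; 4.80 ± 0.72, limma adjusted p = 0.0336). Ly6g was at 142 and 132 CPM in Ctrl ImmN and MatN. edgeR called Ly6g and Il1b. By limma the Ly6g call was lost whichever of the 5 Mx1-Elk1 libraries was left out (smallest adjusted p = 0.0598, without ImmN replicate 1, where Il1b alone was called) and with TMM scaling. The gelatinase granule list was higher in Mx1-Elk1 MatN with 0 of 12 called and 5 adjusted over the list alone (median 1.84, adjusted p = 0.127 with an estimated correlation).

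The difference between the genotypes' steps was tested directly. limma and edgeR called 0 of 24923 genes, with 1654 and 2397 at an unadjusted p under 0.05 (smallest limma adjusted p = 0.329). Ly6g, Abracl and Vim had the smallest p among positive differences and Or8k40, Gcnt3 and Lzts1 among negative ones, and none passed. The specific granule list differed by a median of 1.83 with 0 of 13 called and 3 adjusted over the list alone, 1 of 16 lists higher with the preset correlation. All 16 were lost with the estimated correlation (smallest adjusted p = 0.465). A single fit of all libraries called 1149 genes, but it shares each gene's spread with the progenitor libraries, so no effect is read from that count.

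**Figure D4:**
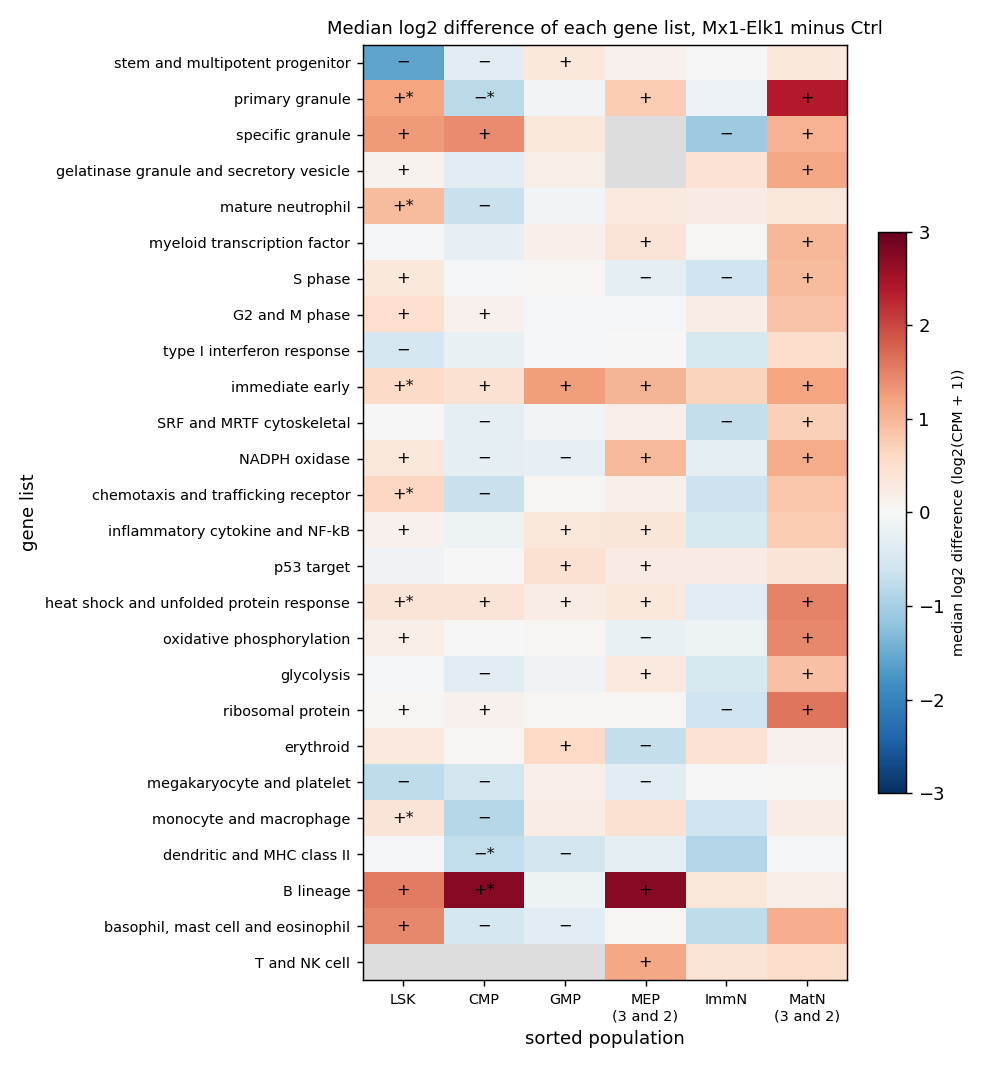
Median log2 difference (Mx1-Elk1 minus Ctrl, log2(CPM + 1)) of each of the 26 gene lists in the 6 populations, with MEP without the library labelled Mx1-Elk1 MEP replicate 1; + and − mark lists called higher or lower by camera with the preset correlation, * those that held with an estimated correlation, and grey lists with fewer than 5 tested members. B lineage genes reach medians of 2.74 in CMP and 2.72 in MEP, and stem and multipotent progenitor genes -1.58 in LSK.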

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

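The tests between populations, the tests of explanations and the use of the MEP fit with 2 libraries labelled Mx1-Elk1 were chosen after the results were seen, while the splits of the libraries were planned before. Several key genes differed between progenitor populations in their Mx1-Elk1 minus Ctrl difference, by a limma test of that difference over 15 key genes and 3 pairs of populations. CMP minus LSK was -3.42 for Mpo (adjusted p = 1.1e-09), -5.51 for Elane (adjusted p = 1.2e-12) and -1.93 for Csf1r (adjusted p = 0.0032). GMP minus CMP was 1.34 for Mpo and 2.10 for Elane (limma adjusted p = 0.0477 and 0.0015). GMP minus LSK was -2.07 for Mpo and -3.41 for Elane, and 1.96 for Fos and 1.14 for Egr1 (limma adjusted p = 3.3e-04, 3.4e-06, 1.0e-04 and 0.0097). No biological explanation of these differences was tested. Single libraries were not tested against their group.

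The library labelled Mx1-Elk1 MEP replicate 1 carried neutrophil transcripts. Cells of MEP type mixed with neutrophils would keep the MEP genes at their share, but 4 of them (Klf1, Car1, Epor and Gata1) stood at a median of 7.22% of the other 2 Mx1-Elk1 MEP libraries, which argues against a mixture with a large MEP share. A wrong label would bring the markers of another sorted population. The mature neutrophil marker mean was 6.85, inside the range of the neutrophil libraries (3.65 to 7.72). The MEP marker mean of 4.68 lay below the other MEP libraries (7.62 to 8.18) but above the neutrophil libraries (2.24 to 4.24). The LSK marker mean of 4.93 was also above the highest neutrophil library (4.17), so progenitor RNA in this library is not excluded. Its mean correlation across 10644 genes was 0.766 with Mx1-Elk1 MatN, 0.745 with Mx1-Elk1 ImmN and 0.740 with Ctrl MatN libraries. The highest single value was 0.7783 in Mx1-Elk1 MatN and 0.7786 in Mx1-Elk1 ImmN, so the correlation does not settle which neutrophil group it resembles most. A wrong label is therefore a candidate explanation, while a MEP share of a few percent stays open: Klf1 at 13.2 CPM was above the 5.34 CPM of the highest neutrophil library, but Car1, Epor and Gata1 at 56.1, 12.6 and 29.6 CPM were within the neutrophil ranges (5.03 to 135, 0 to 12.9 and 11.6 to 68.5 CPM).

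For these counts, S100a8, S100a9 and the genes of the granule, mature neutrophil, chemotaxis, NADPH oxidase and inflammatory cytokine lists were taken out of the set far higher in neutrophil libraries. S100a8, S100a9, Camp, Ngp and Chil3, which rose in CMP, were thus left out. The rest were called lower in Mx1-Elk1 in 111 of 463 cases tested in LSK, 79 of 517 in CMP, 86 of 919 in GMP and 26 of 404 in MEP. They were called higher in 7, 4, 0 and 9 cases (medians of all tested -0.43, -0.37, -0.78 and -0.11). They were 7.74, 33.3, 78.9 and 10.0% of the lower calls in LSK, CMP, GMP and MEP, against 3.79, 4.33, 7.53 and 3.52% of the genes tested. Neutrophils in the Ctrl sorts would bring abundant neutrophil genes, but in Ctrl LSK and CMP 5 such genes reached 15.2 and 8.63% of the level that the set's median share would need (20.47 and 11.7% at the share's lower 95% limit), which argues against whole neutrophils in those sorts. In GMP their Ctrl level was 177% of the level needed, and their Ctrl excess over Mx1-Elk1 was -25.1% of it (SE 10.4). That excess bears on neutrophils only if GMP of both genotypes express these genes alike. In CMP they differed, at 8.68 CPM in Ctrl and 215 CPM in Mx1-Elk1, so neutrophils in the Ctrl GMP sorts stay open. In MEP the 5 genes reached 29.0%, but 59.0% at the lower limit, so neutrophils in the Ctrl MEP sorts cannot be told apart from none. Background in the amplified libraries, with more of it in Ctrl progenitors, would add a common share of each gene's neutrophil level, and 34.2% of the set's tested genes in GMP lay within 2-fold of such a share (24.0, 20.3 and 12.6% in LSK, CMP and MEP). These shares neither match a single background profile nor exclude one, so background cannot be told apart from a biological difference between the genotypes.

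Immediate early genes were called higher in Mx1-Elk1 in 11 of 19 cases in LSK (2 fell), 9 of 19 in CMP, 8 of 19 in GMP and 11 of 17 in MEP, but with an estimated correlation the list's call held in LSK alone (camera adjusted p = 0.0488, against 0.105, 0.121 and 0.168). Scaling would shift all genes alike, but the median difference of all tested genes was at most 1.94% of the list's median (GMP, 0.024 against 1.24), and below 0 in LSK and CMP, which argues against scaling. Handling of the cells that differed between the genotypes would raise chaperones too, and the lowest of the 4 median differences of chaperones was 0.28 (LSK, 7 tested), with 0.50, 0.45 and 0.33 in CMP, GMP and MEP (9, 9 and 8 tested), so different handling may contribute. A higher Elk1 transcript level cannot be told apart from none, since the mean Elk1 difference of 0.18 had an exact stratified p of 0.565 and the transgene's sequence is not described. An effect of the transgene on these genes thus stays open.

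Other splits of the same libraries into groups of the same sizes were fitted with limma. Each comparison has 10 splits, too few for a share under 0.05, and the real split was 1 of the 10. In LSK, CMP, GMP and MatN, and in MEP with 2 libraries labelled Mx1-Elk1, the real counts were 2127, 363, 132, 144 and 620, and the highest other count was 0. For MatN against ImmN in Ctrl the real count was 4 and the highest other 0. In MEP with 6 libraries all 10 splits gave 0 (limma, with 755 genes at an unadjusted p under 0.05 in the real split, and 0 called by edgeR). In ImmN 2 of 10 splits gave at least the real count of 1, and the highest other gave 120. That split set Ctrl replicates 1 and 2 with Mx1-Elk1 replicate 3 against the rest, a structure of the samples that their GMP marker means follow: 4.49, 5.47 and 4.74 in those 3, against 9.63 in Ctrl replicate 3 and 7.51 and 7.23 in Mx1-Elk1 replicates 1 and 2.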

How the results depend on the processing

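The alternatives of the MEP fit without the library labelled Mx1-Elk1 MEP replicate 1 and the fits without the genes far higher in neutrophil libraries were chosen after the data were seen. Where a value changed, the cause was not tested. MEP2 is the MEP fit with 2 libraries labelled Mx1-Elk1.

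Without the filter on low values the counts of genes called were 963 in LSK, 61 in CMP, 39 in GMP, 4 in ImmN, 2 in MatN, 182 in MEP2, and 1 and 0 for MatN against ImmN in Ctrl and in Mx1-Elk1. Shared calls were then 56 (276 in the analysis as reported). They are summed over all pairs of populations, so a gene can count more than once, and use the MEP fit with all its libraries. In one fit of all libraries the counts of genes called were 52 in LSK, 27 in CMP, 18 in GMP, 111 in MEP, 2528 in ImmN, 1059 in MatN, 59 in MEP2, 1271 and 885 for MatN against ImmN in Ctrl and Mx1-Elk1, and 1149 for the difference of these steps. Such a fit shares each gene's spread over all populations, so no effect is read from these counts. edgeR called 82 in GMP, 3 in MatN and 2 for MatN against ImmN in Mx1-Elk1, with 159 shared calls. A minimum log2 difference of 1 left 954 in LSK, a pseudocount of 0.25 CPM 40 in MatN, and TMM scaling 0 for MatN against ImmN in Mx1-Elk1. With TMM the median gene in MEP moved from -0.06 to -0.29. Without the genes far higher in neutrophil libraries 20 were called in GMP. Shared calls summed over the pairs of the 4 progenitor populations were then 111 (212 with those genes). With the estimated correlation 9 of 89 list calls held.

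Replicate numbers did not pair the libraries in the pairs compared: of same-number pairs, 2 of 17 between the genotypes (range -0.163 to 0.203) and 0 of 5 between ImmN and MatN of a genotype (-0.014 to 0.0596) had a correlation over 0.1. Same-number libraries of the progenitor populations of a genotype were not compared with each other. With the number as a block, 232 genes were called in MatN, 1331 in MEP2, and 0 for MatN against ImmN in Ctrl and in Mx1-Elk1, and the ribosomal protein median in MEP2 turned to -0.092.

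Leaving out each library in turn gave 1255 (without Mx1-Elk1 LSK replicate 2) to 2025 in LSK, with 1383 without Ctrl LSK replicate 2, and 156 to 314 in CMP, with 208, 156, 173 and 233 without Ctrl CMP replicates 1, 2 and 3 and Mx1-Elk1 CMP replicate 1. In GMP it gave 29 to 299, with 51, 29 and 299 without Ctrl GMP replicates 1, 2 and 3, and 36 and 34 without Mx1-Elk1 GMP replicates 1 and 2. In MEP it gave 0 to 620, 620 being without Mx1-Elk1 MEP replicate 1. In MEP2 it gave 160 to 977, with 977 and 334 without Ctrl MEP replicates 2 and 3, and 186 and 160 without Mx1-Elk1 MEP replicates 2 and 3. In ImmN it gave 1 to 18, with 2 without Ctrl ImmN replicate 3 and 13, 10 and 18 without Mx1-Elk1 ImmN replicates 1, 2 and 3. In MatN it gave 2 to 306, with 29, 2 and 33 without Ctrl MatN replicates 1, 2 and 3, and 306 without Mx1-Elk1 MatN replicate 3. Where 1 Mx1-Elk1 library remained in MatN or MEP2, the Ctrl libraries alone gave the spread within groups. For MatN against ImmN in Ctrl it gave 1 (without Ctrl ImmN replicate 2 or Ctrl MatN replicate 2) to 7 (without Ctrl ImmN replicate 1), with 2 without Ctrl MatN replicate 1 or 3. In Mx1-Elk1 it gave 0 to 1, with 0 unless Mx1-Elk1 ImmN replicate 1 was the library left out, and the 1 gene was then Il1b and not Ly6g. For the difference of these steps limma gave 0 throughout, with 1654 genes at an unadjusted p under 0.05 and 0 called by edgeR with all libraries. List calls ranged from 73 to 97, the Elk1 difference from 0.13 (without Mx1-Elk1 ImmN replicate 1) to 0.50 (without Mx1-Elk1 ImmN replicate 3), and shared calls from 184 (without Ctrl CMP replicate 2) to 626 (without Mx1-Elk1 MEP replicate 1).

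Among lists called with all libraries or with 1 left out, the direction reversed in 9 cases when a library was left out. The medians of these cases follow. Without Mx1-Elk1 MEP replicate 1, heat shock and ribosomal protein genes in MEP were at 0.33 and 0.063 (lowest values -0.85 and -1.07, without Mx1-Elk1 MEP replicate 2). Without Ctrl ImmN replicate 3, primary granule and ribosomal protein genes in ImmN were at 1.59 and 0.49 (lowest -1.28 and -1.30, without Ctrl ImmN replicate 1). In MatN against ImmN in Ctrl, primary granule, SRF and MRTF and heat shock genes were at 0.44, 0.11 and 0.30 without Ctrl ImmN replicate 3 (lowest -2.72, -0.57 and -1.13, without Ctrl ImmN replicate 1). Ribosomal protein genes in MEP2 were at -0.092 without Ctrl MEP replicate 1 (highest 0.14, without Mx1-Elk1 MEP replicate 3), and in MatN against ImmN in Mx1-Elk1 at -0.37 without Mx1-Elk1 MatN replicate 1 (highest 2.27, without Mx1-Elk1 MatN replicate 3).

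No named gene changed sign where it was called in the main fit or in the alternative. Genes called in neither were counted as the same, whatever their sign. Called among the 346 named values were 98 in LSK, 53 in CMP, 20 in GMP, 1 in ImmN, 31 in MatN and 61 in MEP2, and only these could lose a call. Of them, 67 lost it with edgeR, 136 without the filter, 195 in one fit of all libraries, 33 with a pseudocount of 0.25 CPM and 17 with TMM. In one fit of all libraries 9 other values gained a call. Without the genes far higher in neutrophil libraries 8 lost it in the progenitor fits, where named genes of that set were not counted. Over all fits that left out a library, named values lost their call 356 times, gained it 17 times and stayed the same 1492 times. In ImmN and MatN limma recovered at most 1% of simulated 4-fold or 2-fold changes. Their common dispersions (0.752 and 0.455), and that of MEP with 6 libraries (0.460), were above those in LSK, CMP and GMP (0.0716 to 0.149), and low depth was not separated from this spread.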

Other observations

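The values below were chosen after they were seen, and no explanation was tested. In the 3 Ctrl LSK libraries Ighv1-72 took 57.9, 69.9 and 75.2% of the reads of immunoglobulin heavy variable genes and Igkv10-96 77.4, 97.3 and 80.8% of those of kappa variable genes. In Mx1-Elk1 LSK replicate 3 Igkv10-96 took 96.4% of 331 kappa variable reads, while replicates 1 and 2 had 16 and 0 such reads.

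Xlr4c (chromosome X, 73233688 to 73243130, mm10) was higher by 3.15, 2.63, 2.74 and 3.43 in LSK, CMP, GMP and MEP with 2 libraries labelled Mx1-Elk1, and Wdfy1 (chromosome 1, 79702262 to 79776143) differed by -2.31, -2.35, -1.87 and -2.01. Near-identical Xlr4 genes can share reads in counting, and a strain difference between the genotypes was not tested for Xlr4c, Wdfy1 or Paip1; the labels call the controls littermates in one place and wild type in another.

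In LSK, basophil and mast cell genes rose in 4 of 7 cases and fell in 1 (median 1.45, adjusted p = 0.115 with an estimated correlation), with Mcpt8 from 4.95 ± 0.628 to 27.6 ± 2.96 CPM. In GMP Mcpt8 fell from 248 ± 46.8 to 110.4 ± 10.1 CPM, and the difference between these populations was not tested for this gene. Of the erythroid genes in LSK, Klf1 rose from 7.23 ± 3.96 to 22.8 ± 1.78 CPM while Car2 fell from 1078 ± 123 to 422 ± 23.5 CPM. Paip1 stood at 27.7 CPM in the library labelled Mx1-Elk1 MEP replicate 1.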
